A study of Mus musculus with 10 samples.

How the data were processed

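Granulosa cells were captured by laser microdissection from ovaries of 3-week-old female C57B6/J mice, and polyadenylated RNA was amplified and sequenced by the GEO-seq protocol, a method for low-input RNA from captured tissue areas, per the labels' protocols. The labels put 4 libraries in the group injected with N-acetyl-L-cysteine (NAC, an antioxidant and cysteine source) and 6 in the group injected with saline, and they give batch 1 for all 10. They do not tie a library to an animal, so each library was taken as 1 replicate; p-values measure the spread between captured samples and may be too small if libraries share an animal.

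The authors deposited 1 gene-level table per library, made with Salmon on GRCm38 per the submitters' processing notes; the versions are not given in the sources used here. Each table holds estimated counts (the number of reads Salmon assigned to a gene, which need not be whole), TPM, and an average and an effective transcript length, per the file headers. The tables list 35087 gene symbols and 1548 rows named by a transcript without a symbol. Those rows took 0.496% to 0.638% of the estimated reads of a library and were left out of library sizes and tests. The deposited lengths follow the fragments seen: Gapdh, whose longest annotated transcript has 3289 bases, is listed with lengths of 117 to 173.4 bases, and this enters the deposited TPM. Shared reads were split by Salmon between similar sequences, so values of genes with near-identical copies are uncertain.

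The estimated counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust estimation, TMM factors, default filter for low counts). This left 10945 genes, of which 10695 are annotated as protein-coding. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Log2 fold changes are NAC over saline with standard errors (SE). The SE of a list's median is taken over the members, which are not independent, and does not measure the spread between libraries. CPM are reads scaled to a common library total with the TMM factors, given as mean ± SD. Where a group had 0 reads, the fold is a lower bound against 3 reads over the whole group; such floors cover counting error only, and amplified reads without molecular identifiers are not independent molecules.

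Before the data were examined, 34 gene lists were fixed, of which 31 had at least 4 tested members. Lists were tested against the other genes with camera from limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), with an estimated correlation as the alternative, and with fry, which asks whether a list's genes move on balance one way. For each library a list score was computed as the mean of its members' centred log2 CPM, and group means were compared by an exact two-sided permutation test over the 210 splits of the libraries into 4 and 6; its smallest possible p is 0.00476. All list p-values were adjusted over the lists. Distances between profiles (1 minus Spearman's correlation over tested genes) were compared by an exact one-sided permutation test over the same splits.

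The genes named were also set by a rule fixed with the lists: the 4 genes of the study's title; because fewer than 10 genes passed, the 8 genes in each direction with the smallest unadjusted p and a mean of at least 10 CPM, whether or not they passed; and up to 4 members with the smallest unadjusted p from each list described. Over all lists the rule gives 136 genes, and counts of gene values under alternatives and of libraries apart from the rest cover all of them; the values of 2 of these genes are not reported here. Genes named outside the rule are said to be chosen after their values were seen. Gene positions, types, GC content and transcript lengths came from the GENCODE annotation of GRCm38.

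Alternatives were median-ratio (RLE) factors, library size alone, DESeq2 1.42.0, limma-voom with sample quality weights, log2(TPM + 1) and log2(TPM + 0.1) with limma, effective-length offsets, no low-count filter, a filter of 10 CPM in 4 samples, non-robust estimation, the number of genes detected or the oocyte score as a covariate, each library left out, the replicate number as a block, and other thresholds. Chosen after seeing the data were: NAC 2 and NAC 3 left out together, all libraries thinned to the shallowest, offsets from a smooth trend on GC content and transcript length, distances without NAC 2 and NAC 3, rows without a symbol included, protein-coding genes only, and oocyte and stroma scores as covariates. The offsets were first used with each library's level left in, which moved the median log2 fold of all genes to 0.12; after that result was seen, a version centred to carry no such level was added (median 0.02), and both are given.

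The test was checked on simulated counts with the means, library sizes and spread of the comparison of NAC with saline. Over 10945 genes it recovered 5% of genes changed by 1 on the log2 scale and 48% of those changed by 2, with 1 false call, and made 0 calls when nothing was changed. A list of 20 genes shifted by -1 was recovered by camera, and 0 of 30 random lists were called. The simulated genes varied independently of each other. The check therefore does not cover false calls of lists whose members vary together, such as the oocyte markers (estimated inter-gene correlation 0.853). Both groups were also simulated with the same spread per gene. The NAC libraries were less alike than the saline libraries (median Spearman correlation of pairs 0.670 and 0.878). The counts of false calls therefore do not cover unequal spread between the groups. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom 5.04 to 28.5).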

Results

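The study's title concerns HIF1, FOXO1, Bim and Bcl-XL in follicle atresia, the loss of ovarian follicles through death of their granulosa cells. Transcripts were measured in laser-captured granulosa cells of 3-week-old mice given 150 mg/kg NAC by intraperitoneal injection on 3 consecutive days (4 libraries) or saline (6 libraries), with ovaries taken on day 4. The NAC libraries held 1295412, 509945, 116461 and 1667181 estimated reads (replicates 1 to 4), and the saline libraries 1340324 to 2488408. NAC 2 and NAC 3 stood apart: reads were found for 84.8% and 85.1% of the tested genes, against 97.7% to 99.5% in the other libraries. The median gap between deposited length and effective length in long transcripts, which tracks fragment length, was 276.1 and 305.7 bases, against 210.1 to 235.7.

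**Figure D1:**
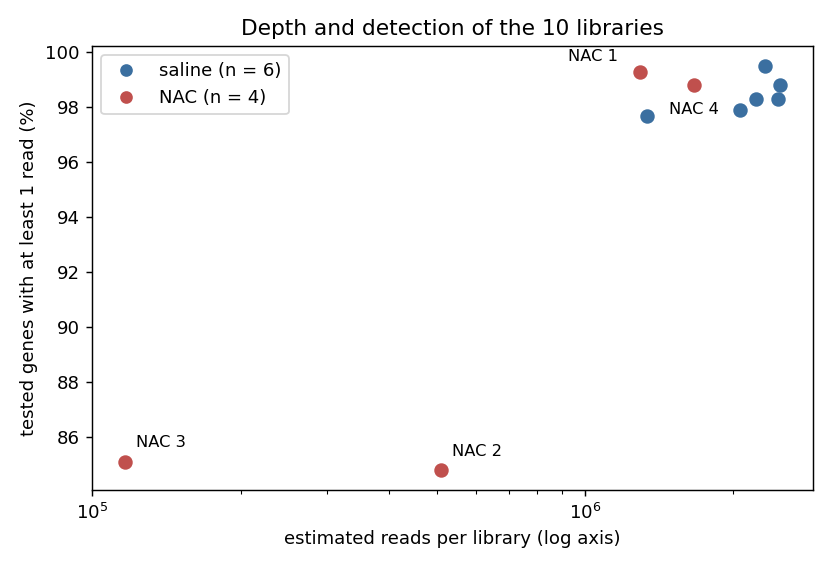
Each point is a library, with its estimated reads on a log axis and the percentage of the 10945 tested genes that had at least 1 read. NAC 2 and NAC 3, at 84.8% and 85.1%, lie below all other libraries.

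The comparison of NAC with saline asked how an antioxidant alters granulosa cell transcripts, and the genes of the title come first. None of these passed edgeR's test. Hif1a, which encodes the oxygen-regulated subunit of HIF-1 (GRCm38 chromosome 12, 73901375 to 73947530), stood at 136 ± 79.9 CPM in NAC (SD, n = 4) and 101 ± 19.3 in saline (SD, n = 6), a log2 fold of 0.36 (SE 0.36, edgeR adjusted p = 0.636). Foxo1, a transcription factor restrained by AKT signalling (chromosome 3, 52268336 to 52353221), had 584 ± 270 CPM in NAC and 968 ± 273 in saline, a log2 fold of -0.71 (SE 0.34). Its unadjusted edgeR p was 0.0494 and its adjusted p 0.307. Bcl2l11, which encodes the pro-apoptotic protein Bim (chromosome 2, 128126038 to 128162547), had 34.0 ± 10.2 CPM in NAC and 33.9 ± 17.3 in saline (log2 fold 0.06, SE 0.45, edgeR adjusted p = 0.964). Bcl2l1, which encodes Bcl-XL and its shorter splice forms (chromosome 2, 152780668 to 152831728), had 44.4 ± 26.3 CPM in NAC and 74.1 ± 19.5 in saline (log2 fold -0.60, SE 0.39, edgeR adjusted p = 0.456). A change of 1 on the log2 scale was recovered for 5% of simulated genes, so changes of this size were mostly not detectable at this depth and spread. The sign of Hif1a turned under 6 alternatives, that of Bcl2l11 under 8 and that of Bcl2l1 under 2, while Foxo1 was negative in all 31. Foxo1 passed under 1 of them, limma-voom with sample quality weights (adjusted p = 0.0401), which gave NAC 3, the shallowest library, the largest weight (2.23). Over all alternatives its adjusted p lay between 0.0401 and 0.731.

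**Figure D2:**
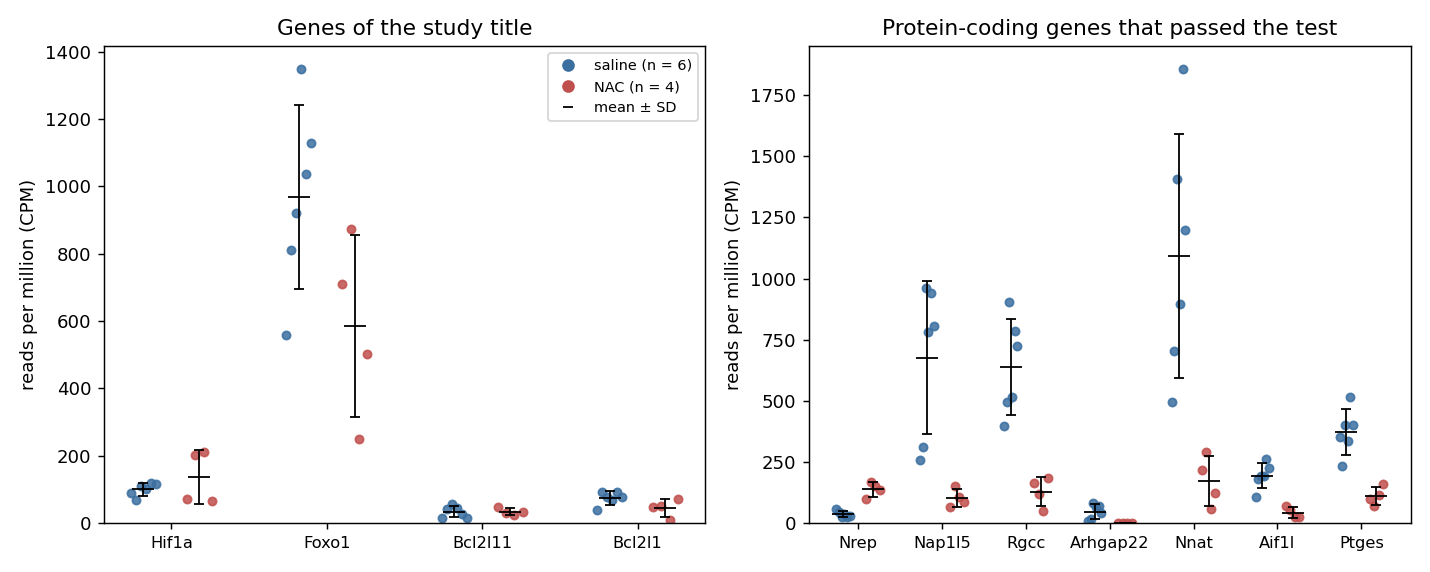
Points are the CPM of each library, with NAC in red and saline in blue; bars give the mean ± SD. The genes of the title overlap between groups, and each of the 7 protein-coding genes that passed has its 4 NAC values entirely above (Nrep) or below the 6 saline values.

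Of the 10945 genes tested, 8 changed between NAC and saline by edgeR's quasi-likelihood test, 2 higher and 6 lower in NAC. Nap1l5, an imprinted gene of the nucleosome assembly protein family (chromosome 6, 58905233 to 58907076), fell from 676 ± 312 CPM (SD, n = 6) to 101 ± 37.0 (SD, n = 4), a log2 fold of -2.76 (SE 0.44, edgeR adjusted p = 0.0374). Nnat, which encodes the membrane protein neuronatin and is also imprinted (chromosome 2, 157560078 to 157562522), fell from 1094 ± 499 to 171 ± 103 CPM, a log2 fold of -2.63 (SE 0.45, edgeR adjusted p = 0.0407). Rgcc, a regulator of the cell cycle (chromosome 14, 79288756 to 79301645), fell from 638 ± 198 to 129 ± 60.1 CPM (log2 fold -2.24, SE 0.36). Aif1l, an actin-binding protein gene (chromosome 2, 31950139 to 31973442), fell by 2.13 on the log2 scale. Ptges, which encodes a prostaglandin E synthase (chromosome 2, 30889471 to 30929863), fell from 373 ± 93.0 to 110 ± 37.2 CPM (log2 fold -1.75). Arhgap22 (chromosome 14, 33214026 to 33369934) had 577 reads over the saline libraries and 0 over the NAC libraries, at least 61.7-fold lower.

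Nrep, a gene first described in neuronal regeneration (chromosome 18, 33437019 to 33464029), rose from 36.4 ± 12.9 CPM in saline to 139 ± 30.4 in NAC, a log2 fold of 1.92 (SE 0.32, edgeR adjusted p = 0.0407). The other gene called higher in NAC, Rps6-ps4, is a processed pseudogene (chromosome 2, 75191073 to 75191822). Salmon assigned it 548 reads over the NAC libraries and 0 over the saline libraries. Its 750 bases are 100% identical to part of the transcript of Rps6, a ribosomal protein gene, so the origin of its reads is uncertain. Its 0 in saline can reflect how shared reads were split, so no lower bound of its fold is given. The next genes by p did not pass. Igfbp5, which encodes an IGF-binding protein, had 459 ± 257 CPM in NAC and 78.2 ± 67.3 in saline (log2 fold 2.54, SE 0.51, edgeR adjusted p = 0.0606). Ahnak, a large scaffold protein gene, had a log2 fold of 1.73, Cst12 of 3.76, Gm21698 of 4.01, 2810039B14Rik of 2.03 and the zinc finger gene Zfp950 of 1.55, with edgeR adjusted p-values of 0.0606 to 0.0642. On the lower side, Fkbp4, which encodes a co-chaperone of steroid receptors, had a log2 fold of -1.43, and Drd4, a dopamine receptor gene, of -3.23, both at an edgeR adjusted p of 0.0529. At an unadjusted p under 0.05 there were 1769 genes, 856 higher and 913 lower, where chance gives 547. The groups did not overlap in 589 tested genes (5.38%, where chance gives 0.952%).

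The calls rested on small margins. Without NAC 3, NAC 4, saline 3, saline 5 or saline 6 the count of 8 became 1, and the gene left was Rps6-ps4 each time. Without saline 4 it became 2, Rps6-ps4 and Fbxw24. In none of these fits did a protein-coding gene among the 8 keep its call. Without saline 2 the count became 5. Without NAC 1, NAC 2 or saline 1 it became 58, 39 and 22, with all 8 genes kept in each. With NAC 2 and NAC 3 left out together, 2 genes passed, of which Rps6-ps4 was shared.

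Genes that HIF-1 can induce were described in 2 lists. The 19 HIF-1 responsive glycolysis genes had a median log2 fold of -0.95, and 14 were negative; 0 passed over all genes tested, and 6 passed adjusted over the list alone, all lower in NAC. Pfkl, which encodes liver-type phosphofructokinase, had 94.8 ± 38.1 CPM in NAC (SD, n = 4) and 237 ± 47.6 in saline (SD, n = 6; log2 fold -1.26). Pkm, pyruvate kinase, had 487 ± 182 and 1138 ± 282 CPM. Tpi1, triosephosphate isomerase, had 403 ± 151 and 780 ± 89.4, and Slc2a1, the glucose transporter GLUT1, 21.6 ± 5.94 and 63.4 ± 34.1. As a group these genes fell relative to the other genes in limma's camera test (adjusted p = 0.000395; adjusted p = 0.311 with an estimated correlation). Their score per library was lower in NAC by 0.964 on the log2 scale (exact permutation p = 0.00476, the smallest it can give; adjusted p = 0.0369). A trend with GC content ran through the same comparison: with genes in 4 equal groups by GC content, the median log2 fold was 0.44 in the group with the lowest GC content and -0.41 in that with the highest. With offsets for GC content and transcript length, chosen after seeing the data, the median of the glycolysis genes was -0.43 with each library's trend centred (camera adjusted p = 0.0119) and -0.20 with its level left in (camera adjusted p = 0.0303). Over all alternatives the adjusted p lay between 1.48e-06 and 0.311.

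The 20 tested members of the list of other HIF-1 responsive genes had 10 positive and 10 negative values with a median of -0.05, and camera did not call it (adjusted p = 0.636). P4ha2, a collagen prolyl hydroxylase subunit gene, had 5.80 ± 6.79 CPM in NAC and 42.6 ± 17.1 in saline, and was the 1 member that passed adjusted over the list alone; 0 passed over all genes. Bhlhe40, a transcriptional repressor gene, had a log2 fold of -1.69, Mif, a cytokine gene, of -0.96 and Hilpda, a lipid droplet protein gene, of 0.81. The value of Hilpda rested on NAC 2, which had 151.5 CPM, and was -0.07 without that library. The median of the list turned positive without saline 3, saline 4 or saline 5 (range -0.22 to 0.19 over the libraries left out). The score of this list was lower in NAC by 0.458 (exact permutation p = 0.00476, adjusted p = 0.0369), with -0.738 in NAC 3 and -0.152 to -0.0651 in the other NAC libraries. On log2(TPM + 1) the difference was -0.294 (exact permutation p = 0.0714, adjusted p = 0.185), and 0 of the 31 list scores passed on that scale, with a smallest adjusted p of 0.0984.

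The BCL2 family and the caspases were described because the title names Bim and Bcl-XL. Among the 7 tested pro-apoptotic members, 5 were negative, 0 passed over all genes and 2 passed adjusted over the list alone, Bad and Bid, which encode BH3 proteins. Bad had 26.0 ± 12.8 CPM in NAC (SD, n = 4) and 74.8 ± 27.9 in saline (SD, n = 6; log2 fold -1.42), and Bid 27.6 ± 10.7 and 63.3 ± 17.9 (log2 fold -1.20). Bax and Bok, which encode pore-forming members, had log2 folds of -0.74 and -0.64. Camera gave this list an adjusted p of 0.0822 and the exact permutation test of its score an adjusted p of 0.0633, so neither passed. Of the 5 tested anti-apoptotic members, 4 were positive and 0 passed by either adjustment: Mcl1 had 92.4 ± 64.6 CPM in NAC and 47.5 ± 9.84 in saline (log2 fold 0.92), Bcl2 a log2 fold of 0.76 and Bcl2l10 of 1.17 (camera adjusted p = 0.274). Bcl2l10 had 309.5 CPM in saline 4 and 95.13 in saline 2, the saline libraries with the most oocyte marker reads, and under 1 in the other saline libraries. Without NAC 2 and NAC 3, the log2 fold of Mcl1 was -0.11. With centred GC and length offsets that of Bok was 0.06. With each library's level left in, the log2 folds of Bok and Bax were 0.20 and 0.08. The 25 tested caspase and death receptor genes had a median of 0.05, a mean of -0.03 and a camera test that pointed down (adjusted p = 0.732). Their median was -0.17 to 0.10 with each library left out and negative in 8 of these 10 cases. In that list, with 0 members past either adjustment, Tnfrsf1a, a TNF receptor gene, had a log2 fold of -1.08, Fadd, a death receptor adaptor gene, of -1.18, Ripk1 of 1.29 and Cycs, which encodes cytochrome c, of 0.94.

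Genes that FOXO factors can induce were divided, with 10 of 19 positive and a median of 0.06 (camera adjusted p = 0.732), although their score was lower in NAC by 0.176 (exact permutation p = 0.514). The median was -0.10 to 0.30 with each library left out, and negative without NAC 1, saline 1, saline 3 or saline 6. None passed over all genes, and 1 passed adjusted over the list alone, Klhl24, a ubiquitin ligase adaptor gene, with 59.8 ± 38.4 CPM in NAC (SD, n = 4) and 14.4 ± 7.82 in saline (SD, n = 6). Map1lc3b, an autophagosome protein gene, had a log2 fold of -0.73, Rictor, a subunit gene of mTORC2, of 0.80 and Pik3ip1, a PI3K inhibitor gene, of 1.35.

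Glutathione, thioredoxin and NRF2 responsive genes were described because NAC supplies cysteine for glutathione. Of 44 tested, 30 were negative, with a median log2 fold of -0.53; 0 passed over all genes. Adjusted over the list alone, 7 passed as lower and 1 as higher. Gpx1, glutathione peroxidase, had 109 ± 84.6 CPM in NAC (SD, n = 4) and 519 ± 164 in saline (SD, n = 6; log2 fold -2.18). Gpx4, the lipid peroxide-reducing form, had 267 ± 93.4 and 679 ± 223, Prdx6, a peroxiredoxin, 204 ± 44.7 and 476 ± 143, and Fth1, ferritin heavy chain, 1356 ± 307 and 2924 ± 745. The member that passed as higher, named after its value was seen, was Gclm, which encodes the modifier subunit of glutamate-cysteine ligase (log2 fold 1.02, adjusted p = 0.0260 over the list alone). The list fell in camera (adjusted p = 0.00854; adjusted p = 0.563 with an estimated correlation). Camera did not call it without NAC 1 (adjusted p = 0.0569), with thinning to the shallowest library (0.0769), with oocyte and stroma scores as covariates (0.0857) or with GC and length offsets with the level left in (median -0.19, adjusted p = 0.0641). With centred offsets it did (median -0.27, adjusted p = 0.0329). Its score was lower in NAC by 0.612 (exact permutation p = 0.00476, adjusted p = 0.0369).

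A further 3 lists fell in camera with the preset correlation, each without a member past the threshold over all genes. The 21 tested unfolded protein and ATF4 responsive genes had 18 negative values and a median of -0.32 (camera adjusted p = 0.0430; adjusted p = 0.563 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Herpud1, a gene of endoplasmic reticulum degradation, had a log2 fold of -1.25, Phgdh, the entry enzyme of serine synthesis, of -0.91, Creld2 of -0.70 and Sdf2l1 of -0.78. The 39 nuclear respiratory chain genes had a median of -0.28 (camera adjusted p = 0.0365; adjusted p = 0.563 with an estimated correlation), and adjusted over the list alone 3 passed as lower and 1 as higher. Atp5b, a subunit of ATP synthase, had 1020 ± 341 CPM in NAC (SD, n = 4) and 2443 ± 1010 in saline (SD, n = 6), Cyc1 a log2 fold of -1.14 and Uqcrb of 1.18. The 85 tested ribosomal protein genes had 62 negative values and a median of -0.40 (camera adjusted p = 0.00398; adjusted p = 0.670 with an estimated correlation), with 4 lower adjusted over the list alone. Rplp0 had 1883 ± 680 and 6026 ± 2486 CPM, and Rps2, Rps26 and Rpl41 had log2 folds of -1.39, -1.28 and -1.61. With GC and length offsets with the level left in, camera called none of the 3: the medians were -0.15 for the unfolded protein genes (adjusted p = 0.396), -0.13 for the respiratory chain (adjusted p = 0.0641) and -0.09 for the ribosomal protein genes (adjusted p = 0.0641). With centred offsets the unfolded protein genes were not called (adjusted p = 0.132), and the others were (adjusted p = 0.0164 for each). Calls of all 3 were also lost with thinning (adjusted p = 0.565, 0.172 and 0.0769, in the same order), with the oocyte score as a covariate (0.0944, 0.256 and 0.08) and with the replicate block (0.0736, 0.174 and 0.0960). The unfolded protein and respiratory chain calls were lost with library size alone (0.123 and 0.114), a strict filter (0.0631 and 0.0539) and both scores as covariates (0.598 and 0.0857), and the unfolded protein call with RLE factors (0.0515). Without NAC 1, NAC 4 or saline 1 the unfolded protein call was lost (adjusted p = 0.130, 0.184 and 0.0565), and without NAC 3 its median was -0.64. Without NAC 1, NAC 3, NAC 4 or saline 6 the respiratory chain call was lost (adjusted p = 0.130, 0.0514, 0.0862 and 0.0520), and without NAC 2 its median was -0.47. Without NAC 4 the ribosomal protein call was lost (adjusted p = 0.0544). The scores of the unfolded protein and respiratory chain lists passed the exact permutation test (adjusted p = 0.0369 and 0.0492), and that of the ribosomal protein genes did not (adjusted p = 0.179).

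**Figure D3:**
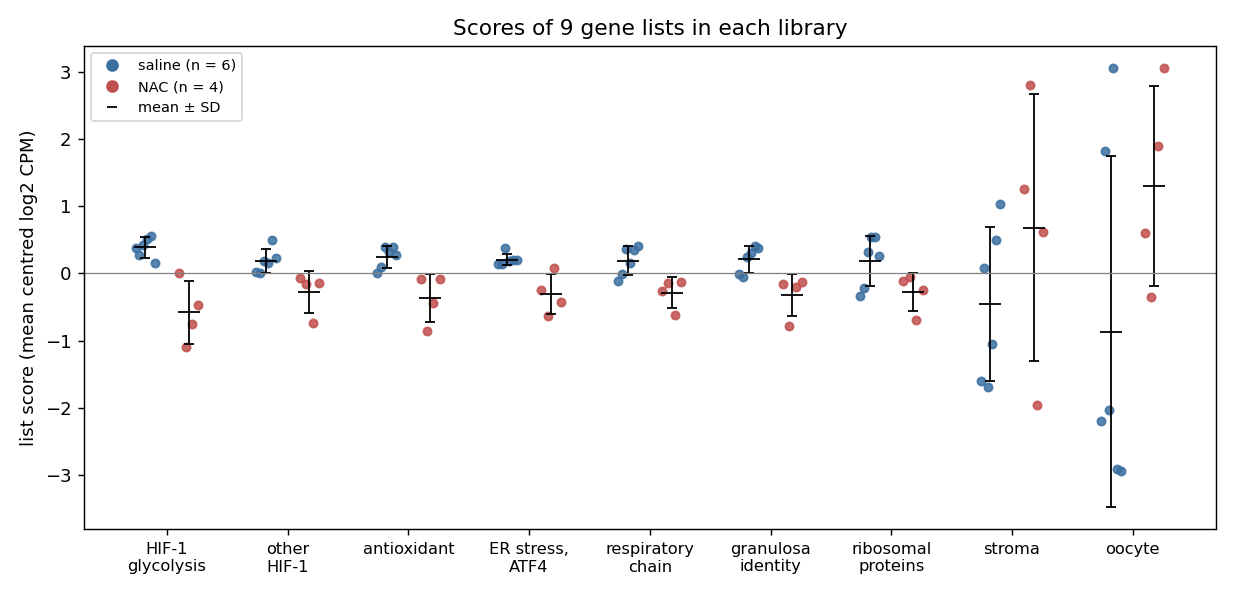
Points are the score of each list in each library (mean centred log2 CPM), NAC in red and saline in blue, with the mean ± SD as bars. The 4 NAC scores of the HIF-1 responsive glycolysis list lie below the 6 saline scores, while oocyte scores spread from -2.94 to 3.06 in saline.

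Granulosa cell identity was described with 28 genes, of which 19 were negative with a median of -0.37. Over all genes 1 passed, Nap1l5, and adjusted over the list alone 8 passed as lower and 1 as higher. Inha, which encodes the inhibin alpha subunit, had 6315 ± 2599 CPM in NAC (SD, n = 4) and 23337 ± 11363 in saline (SD, n = 6; log2 fold -1.89, edgeR adjusted p = 0.0924). Hsd17b1, an estradiol-forming enzyme gene, had 336 ± 153 and 1087 ± 383 CPM (log2 fold -1.68, edgeR adjusted p = 0.0748). The member that passed as higher adjusted over the list alone was Igfbp5. Camera did not call the list (adjusted p = 0.155), while its score was lower in NAC by 0.531 (exact permutation p = 0.00952, adjusted p = 0.0492). In 1 of 26 alternatives, the fit without a low-count filter, camera called it as lower (adjusted p = 0.0203). Among 11 tested genes with textbook links to atresia, 8 were positive with a median of 0.45 (camera adjusted p = 0.0764), 0 passed over all genes, and Igfbp5 and Cald1, an actin regulator gene (log2 fold 2.03), passed as higher adjusted over the list alone. Sparc, a matrix protein gene, had a log2 fold of 1.03 and Clu, which encodes clusterin, of -0.65. The granulosa identity and atresia lists share Igfbp5. Cald1 and Sparc had their lowest NAC values in NAC 3 (40.27 and 177.2 CPM), where the stroma score was also lowest (-1.96). That score was -1.69 to -1.05 in saline 1, saline 3 and saline 4. There Cald1 had 10.39 to 12.69 CPM, against 39.46 to 76.02 in the other saline libraries. Igfbp5 instead had its highest value in NAC 3 (724.9 CPM). For Cald1 and Sparc, stromal RNA cannot be told apart from a change in granulosa cells. Camera called the atresia list in 7 of 26 alternatives (adjusted p 0.0140 to 0.563 over all): without NAC 3 (0.0168), saline 3 (0.0488), saline 5 (0.0321) or saline 6 (0.0397), with the replicate block (0.0140) and with GC and length offsets (0.0168 centred, 0.0382 with the level left in). Without NAC 2 its median was 0.29 (adjusted p = 0.263).

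Markers of other ovarian cells were measured because a captured area can hold them. The 22 tested oocyte markers had 20 positive values and a median of 0.99, and rose in camera (adjusted p = 4.2e-06; adjusted p = 0.563 with an estimated correlation), but 0 passed by either adjustment and the exact permutation test of the score gave p = 0.162. The median of the oocyte markers was 0.02 without NAC 4 and 2.23 without saline 4, with camera's call kept in each (adjusted p = 0.00100 and 1.51e-13). The summed CPM of the 24 listed markers, without TMM factors, varied within both groups, from 602 to 3750 in NAC and from 43.7 to 2970 in saline. Nlrp14 had 142 ± 104 CPM in NAC (SD, n = 4) and 21.6 ± 41.5 in saline (SD, n = 6), Nlrp5 58.3 ± 59.4 and 8.72 ± 16.6, Dppa3 104 ± 64.0 and 21.4 ± 32.1, and Oosp1 a log2 fold of 1.87. All 16 stromal fibroblast and smooth muscle markers were positive, with a median of 1.68 (camera adjusted p = 0.00243; adjusted p = 0.563 with an estimated correlation; score, exact permutation p = 0.271), and 4 passed as higher adjusted over the list alone and 0 over all genes. Of these, Myh11, smooth muscle myosin, had a log2 fold of 3.55, Mfap5 of 3.21, Ogn of 2.81 and Rgs5, a pericyte marker, of 3.33, with the highest NAC value in NAC 2 for each. Without NAC 2 the median of the stromal markers was 0.85 and camera did not call them (adjusted p = 0.201). The 6 tested endothelial markers had a median of 1.04 and did not pass with all libraries (camera adjusted p = 0.0879), with 1 higher adjusted over the list alone: Pecam1 had a log2 fold of 1.70, Kdr of 2.12, Emcn of 2.29 and Eng of 0.38, which was -0.25 without NAC 4. Camera called the endothelial markers in 9 of 25 alternatives (adjusted p 0.00097 to 0.699 over all), among them without NAC 3 (0.00097), saline 5 (0.0161) or saline 6 (0.0309), and without NAC 1 their median was 1.83. No leukocyte marker was abundant enough to be tested, and 2 erythroid and 2 surface epithelium markers were, so these lists were not tested as sets with all libraries. With fewer NAC libraries the filter asks for reads in fewer libraries, and more markers enter. Without NAC 2 and NAC 3, Upk3b, Krt19 and Msln entered with reads in NAC 1 and NAC 4 and 0 in every saline library. Cdh1 entered with its most reads in saline 4 (22). The direction of a member that enters through NAC libraries alone is set by the filter. Camera's results with NAC libraries left out therefore do not test a rise of these lists in NAC. Without NAC 2 and NAC 3, 8 surface epithelium markers were higher in NAC in camera (adjusted p = 3.73e-08; adjusted p = 0.0249 with an estimated correlation), as were 5 erythroid markers (0.00806; 0.412 with an estimated correlation). Both lists also passed without NAC 2 (adjusted p = 0.0314 for each), and the surface epithelium list passed without a low-count filter (0.0368), where the erythroid (0.0794) and leukocyte lists (0.0858) did not. The erythroid list did not pass without NAC 1 (0.198), NAC 3 (0.0946) or NAC 4 (0.573). The 9 surface epithelium markers not tested with all libraries had a summed CPM, without TMM factors, of 126 in NAC 1, 75.4 in NAC 4, 0 in NAC 2, 17.3 in NAC 3 and 0.751 to 13.5 in saline. The 6 such erythroid markers had 953 in NAC 4, 51.3 in NAC 1, 0 in NAC 2 and NAC 3 and 0 to 88.6 in saline.

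The remaining 16 lists did not pass camera with all libraries and the main settings. Median log2 folds, with the range when each library was left out in brackets, were 0.74 (0.05 to 0.90) for 5 late antral and ovulatory granulosa genes and -0.14 (-0.58 to -0.07) for 14 steroid synthesis genes. They were -0.44 (-0.79 to -0.24) for 24 cholesterol genes, -0.13 (-0.31 to -0.08) for 26 DNA replication genes and -0.16 (-0.30 to -0.10) for 30 mitosis genes. They were -0.27 (-0.47 to -0.20) for 16 p53 responsive genes, -0.15 (-0.65 to 0.00) for 21 immediate early and heat shock genes, -0.33 (-0.47 to -0.27) for 29 autophagy and lysosome genes and 0.41 (0.12 to 0.52) for 13 mitochondrially encoded genes. The last of these turned to -0.48 with centred GC and length offsets (camera adjusted p = 0.00652), to -0.35 with the level left in (camera adjusted p = 0.0300) and to -0.40 without NAC 2 and NAC 3 (camera adjusted p = 0.152). The other medians were 0.49 (-0.54 to 0.81) for 5 oxidant-producing enzymes, 0.25 (0.08 to 0.36) for 28 TGF-beta family genes, 0.46 (0.27 to 0.53) for 27 PI3K and insulin pathway genes and 0.92 (0.60 to 1.03) for 22 extracellular matrix genes. They were 0.36 (-0.06 to 0.48) for 10 theca markers, -0.14 (-0.37 to 0.13) for 4 luteal markers and -0.27 (-0.43 to -0.20) for the 4 title genes. The lowest medians of the steroid synthesis, cholesterol, p53, immediate early, late antral and title lists were those without NAC 1. The sign turned for the oxidant-producing enzymes without NAC 4, for the theca markers without NAC 2, for the immediate early genes without saline 5, and for the luteal markers without NAC 3, saline 5 or saline 6. Camera called the extracellular matrix list in 9 of 26 alternatives (adjusted p 0.00108 to 0.864), among them without NAC 3 (0.00108), saline 2 (0.0437), saline 5 (0.0237) or saline 6 (0.0298). It called the cholesterol list in 5 of 25 (adjusted p 0.00806 to 0.982), among them without NAC 3 (0.0168) or saline 2 (0.0441). Without NAC 2 and NAC 3 it also called the DNA replication (0.00806), mitosis (0.0131) and autophagy lists (0.0166), and without a low-count filter the autophagy list (0.0226). Of the members of these 16 lists, 0 passed over all genes. Adjusted over the list alone, 11 passed as higher and 11 as lower, in 10 of the lists. Among these, Rgs2, a G-protein regulator gene of the late antral list, passed with 2340 ± 786 CPM in NAC (SD, n = 4) and 923 ± 288 in saline (SD, n = 6), as did Igf1 with 559 ± 144 and 246 ± 95.8. Mcm5, a replication licensing gene, passed with 73.3 ± 37.4 and 212 ± 50.2 CPM, Ctsl, a lysosomal protease gene, with 1646 ± 333 and 5139 ± 2306, and Sqstm1, an autophagy receptor gene, with 230 ± 74.7 and 483 ± 80.3. For the TGF-beta family, PI3K and theca lists the score pointed the other way, with differences of -0.06, -0.06 and -0.03. Score differences lay below the median log2 fold for the mitochondrially encoded genes (0.03 against 0.41) and above it for the oocyte markers (2.17 against 0.99). A member with 0 reads lowers the score of its library, and NAC 2 and NAC 3 had reads for the fewest tested genes (84.8% and 85.1%). How far this moved the scores was not tested.

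Whole profiles were compared by their distances. The mean distance between groups exceeded that within groups by 0.0863 (exact one-sided permutation p = 0.00476, the smallest it can give). Median Spearman correlations over genes, which are not independent replicates, were 0.878 between pairs of saline libraries, 0.670 between pairs of NAC libraries and 0.775 between the groups. NAC libraries were thus less alike than NAC and saline libraries were. With all libraries the excess rested on the close saline pairs, so its p can reflect unequal spread and does not by itself show separation by treatment. NAC 2 correlated best with NAC 3 (0.655), at 0.636 with saline 6 and at 0.580 and 0.616 with NAC 1 and NAC 4, and NAC 1 at 0.842 with saline 1 and 0.843 with NAC 4. Without NAC 2 and NAC 3 the excess was 0.0508 (exact permutation p = 0.0357, the smallest that 28 splits can give). Of 8 measures of a library, 3 had an exact permutation p under 0.05 between groups. Total reads were lower in NAC (exact permutation p = 0.00952). Reads in 3 mitochondrial-like nuclear pseudogenes, Gm29216, Gm20594 and Gm10925 (chosen after their values were seen), made up 1.81% ± 0.522 in NAC (SD, n = 4) and 1.035% ± 0.222 in saline (SD, n = 6, exact permutation p = 0.00952). Since they were picked on these values, that p is descriptive only. Gm10925 lies wholly within the transcript of mt-Atp6, so its reads can be mitochondrial. Reads in mitochondrial genes made up 3.16% ± 1.45 in NAC and 2.522% ± 0.582 in saline (exact permutation p = 0.352). The median correlation of a library with the others was 0.738 ± 0.0965 (SD, n = 4) and 0.842 ± 0.00829 (SD, n = 6; exact permutation p = 0.00476, the smallest it can give). The adjusted p was 0.0254 for each of the 3.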

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

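Chosen only after results were seen were the tests on Rps6-ps4 and on the oocyte markers, the centred form of the GC and length test, and the fit without NAC 2 and NAC 3. Thinning, the form of the GC and length offsets run first and the covariates for both oocyte and stroma scores were added after seeing the data, with their bounds set before their own results.

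Regroupings of the libraries asked whether chance gives as many calls. Of 100 splits of the 10 libraries into 4 and 6, the real one included, 2 gave at least 8 genes past the threshold, and 1 gave at least 1769 genes at an unadjusted p under 0.05 (highest other 1432). These shares are under 0.05, so a chance regrouping of independent libraries rarely gives either count, but the labels do not show that the libraries are independent. Splits that put NAC 2 and NAC 3 with 2 saline libraries gave 477 to 1291 genes at an unadjusted p under 0.05. The median over the other splits was 252. The regroupings thus cannot separate treatment from 2 shallow libraries that both lie in the NAC group. The highest other split called 29 genes, all higher in NAC 3, NAC 4, saline 2 and saline 4. Of these genes 5 are in the fixed oocyte list, and the rest were not sorted by cell type. These 4 libraries had the most oocyte marker reads, 1520 to 3750 summed CPM without TMM factors, against 43.7 to 680 in the others. This split thus follows the oocyte marker level of the captures and not treatment, and it calls more genes than treatment does. For the 7 lists past camera's threshold, 17 of the 100 splits gave as many, the highest other split 14, so chance cannot be excluded for that count.

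The lower level of the HIF-1 responsive glycolysis genes in NAC was weighed against depth, GC content and oocyte or stromal RNA. The SE given here are over list members and do not measure the spread between libraries. The tables argue against read number as the whole cause. With every library thinned to the shallowest, the median log2 fold of the 10 members still tested was -0.676 (SE 0.152) in the median of 5 draws. That lies below the bound of -0.5 set beforehand. The draw nearest 0 gave -0.615 (SE 0.177), within its error of that bound. Thinning equalises reads and not captured molecules. NAC 2 held reads for 10419 genes from 509945 estimated reads, and NAC 3 for 10222 from 116461. Thinning thus does not cover fewer captured molecules in NAC 2. Without NAC 2 and NAC 3 the median was -0.745 (SE 0.163). The median was -0.86 (SE 0.272) when both oocyte and stroma scores were covariates. This argues against RNA of these cells as the whole cause, within what 10 libraries with 2 covariates can separate. Endothelial, surface epithelium and erythroid RNA were not in that fit. GC content and transcript length stay open: the form of the offsets run first, with each library's level left in, gave -0.201 (SE 0.199), above the bound of -0.3 set before that form was run for a GC cause, though within its error of it. That form also moved the median of all genes to 0.119, so a centred form was added after this was seen; it gave -0.434 (SE 0.18), between the bounds. A GC trend of amplification may account for part or most of the difference, and an effect of NAC stays open beside it.

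Rps6-ps4 had reads in all 4 NAC libraries and 0 in the 6 saline libraries. Reads of Rps6 assigned to the pseudogene are a candidate explanation for its reads, since it is 100% identical to the Rps6 transcript over its length. Among the 40 pseudogenes lying wholly within another gene's coding transcript, 2 others took shares of the reads that separated the groups, Gm13835 lower and Rps12l1 higher in NAC (chosen after their values were seen). A group-wide difference in how shared reads were assigned cannot be told apart from other causes on so few pseudogenes, and an effect of NAC was not tested.

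The oocyte markers differed between captures of the same group. They varied together within groups, with an estimated inter-gene correlation of 0.853, which is consistent with oocyte RNA in some captures; laser capture of granulosa cells would be meant to leave oocytes out. The most abundant marker, H1foo (chosen, like Gdf9, after its values were seen), had 221 ± 175 CPM in NAC (SD, n = 4) and 95.9 ± 157 in saline (SD, n = 6), and Gdf9 had 117 ± 122 and 110 ± 190. An effect of NAC on the oocyte share cannot be told apart from this variation with so few libraries (exact permutation p of the score = 0.162).

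Libraries far from the rest of their group were looked for in 350 sets of values, 33 of which had such a library, where chance gives about 17.5; 9 were in NAC 2 and 8 in NAC 3. Saline 1 held 1340000 reads where the next lowest saline library held 2068000. NAC 2 was highest for Hilpda (151.5 CPM), Uqcrb (292.8), Smad1 (86), Myh11 (200.7), Mfap5 (176.1), Ogn (149.5) and Rgs5 (110.6), highest for the score of mitochondrially encoded genes (0.852) and lowest for that of granulosa identity (-0.787). NAC 3 was highest for Perp (233.6 CPM) and for the scores of DNA replication (0.101) and mitosis genes (0.155). It was lowest for the scores of other HIF-1 responsive genes (-0.738), FOXO responsive genes (-0.692), TGF-beta family genes (-0.719) and extracellular matrix genes (-0.871). NAC 4 was lowest for Creld2 (123.5 CPM), and NAC 1 was lowest for Oosp1 (20.2 CPM) and highest for Cdkn1a (13.71, with 0 in the other NAC libraries). Saline 4 was highest for Pik3ip1 (29.29 CPM), Bcl2l10 (309.5), Nlrp5 (41.5) and Nlrp14 (104). Saline 1 was highest for Igfbp5 (209.8 CPM) and lowest for the score of the title genes (-0.536). Saline 2 was highest for Gm21698 (11.77 CPM) and Ogn (26.84) and lowest for the score of cholesterol genes (-0.401). Saline 3 was highest for the score of unfolded protein genes (0.374), saline 5 for Rgs5 (10.76 CPM) and saline 6 for Myh11 (14.67 CPM).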

How the results depend on the processing

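Alternatives chosen after seeing the data are the shallow libraries left out together, thinning, GC and length offsets, rows without a symbol, protein-coding genes and the covariates for both oocyte and stroma scores. Rps6-ps4 kept its call in all 30 settings that tested it and Arhgap22 in 18 of 30. Of 31 settings, Nap1l5 and Rgcc kept theirs in 20, Nnat and Nrep in 17 and Aif1l and Ptges in 14, and none of these 8 genes changed sign. For the 136 genes under the naming rule, 3758 of 4129 values kept direction and call, 189 gained a call, 96 lost it, and 86 values of 26 genes took the opposite sign with no call in either. Hif1a was among these, with log2 folds of -0.63 to 0.65. Library size alone moved the median log2 fold of all genes to 0.19, from 0.02.

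The 8 genes (2 higher, 6 lower) became 441 with DESeq2 (189 and 252), 476 with limma-voom and sample weights (264 and 212), 226 without a low-count filter (94 and 132), 42 with genes detected as a covariate (5 and 37) and 183 at an adjusted p under 0.1 (61 and 122). They became 12 with log2(TPM + 1) (1 and 11), 6 with log2(TPM + 0.1) (1 and 5), 5 with effective-length offsets (2 and 3) and 1 with the oocyte score as a covariate (1 and 0, with 1526 genes at an unadjusted p under 0.05). Leaving out each library gave 1 to 58 genes, 1 to 16 higher and 0 to 42 lower. Among later choices they became 2 without NAC 2 and NAC 3 (1 and 1) and 43 with thinning (18 and 25, in the median of 5 draws that gave 35 to 60). The count was 3 with GC and length offsets (1 and 2), 5 with the level left in (2 and 3) and 7 for protein-coding genes (1 and 6). It was 1 with both scores (1 and 0, with 752 at an unadjusted p under 0.05). The gene left with the oocyte score or with both scores was Rps6-ps4. Fewer samples and fewer genes tested enter some of these by construction; otherwise the cause was not tested. With the replicate number as a block, 1 gene passed, Rps6-ps4 (1 higher and 0 lower, with 805 at an unadjusted p under 0.05). In that fit 7 lists passed, of which 4 were shared. The numbers do not pair the libraries: deviations of the equally numbered NAC and saline libraries correlated at -0.0081, 0.0105, 0.00932 and 0.196, and not every library correlated best with its own number.

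The 7 lists past camera's threshold became 0 with an estimated correlation (1 at an unadjusted p under 0.05; smallest adjusted p 0.311), 4 with fry, 12 without a filter, 3 with the oocyte score as a covariate, 4 to 10 with each library left out, 15 without NAC 2 and NAC 3, 1 with thinning and 2 with both scores; the cause was not tested. HIF-1 responsive glycolysis kept its call in 26 of 27 settings (adjusted p 1.48e-06 to 0.311), antioxidant genes and oocyte markers in 22, ribosomal proteins in 20, and unfolded protein and respiratory chain genes in 14; stroma markers kept it in 22 of 26. The mitochondrially encoded genes turned from a median of 0.41 to a called -0.48 with GC and length offsets, or -0.35 with the level left in, and to -0.40, not called, without NAC 2 and NAC 3. The 6 list scores past the exact permutation test became 0 with log2(TPM + 1), where 8 had an unadjusted p under 0.05. The distance between groups passed in all 3 alternatives (0.0688, 17.7 and 0.0508 in their own units). Depth is a limit for genes with few reads, as NAC 3 held 116461 reads.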

Other observations

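The mitosis genes, the values per library and the GC correlations were chosen after their values were seen; the test on imprinted genes followed the calls of Nap1l5 and Nnat. The mitosis genes held members that differed in opposite ways although their list did not pass. Cdc20, an activator of the anaphase-promoting complex, had 121 ± 75.0 CPM in NAC (SD, n = 4) and 375 ± 119 in saline (SD, n = 6), with a log2 fold of -1.63 (SE 0.42, edgeR adjusted p = 0.0970). Aurka and Aurkb, which encode mitotic kinases, had log2 folds of -1.27 and -1.10, and Ndc80, a kinetochore gene, of 1.20 with all 4 NAC values above the 6 saline values. Adjusted over the list alone, 3 of 30 passed as lower and 1 as higher, and 0 passed over all genes.

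Inha differed among saline libraries as well as between groups. It stood at 7606 CPM in saline 1 and 10270 in saline 2, the first within and the other above the NAC range of 2586 to 8216, and at 28030 to 32860 in the other saline libraries. Nap1l5 had 257 and 311 CPM in saline 1 and saline 2, 782 to 960.5 in the other saline libraries and 65.7 to 152 in NAC. Some other named genes were also lowest in saline 1 and saline 2 among saline libraries. Atp5b had 1313 and 1013 CPM there, 2751 to 3237 in the other saline libraries and 640 to 1442 in NAC. Rpl41 had 814 and 656, 2167 to 3128 and 379 to 842, in the same order. Others were not, such as Tpi1, with 804.5 and 646.6 in saline 1 and saline 2 and 758.4 to 923.8 in the rest. Atp5b and Rpl41 thus differed within saline in the direction of the group difference.

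GC content was related to each library's deviations from the mean profile across genes, which are not independent replicates. Spearman's correlation with GC content was -0.496 in NAC 2 and -0.34 in NAC 3, 0.201 and 0.0961 in NAC 1 and NAC 4, and 0.0857 to 0.423 in saline. Of the log2 folds between groups, the correlation with GC content across 10851 genes was -0.437, and with transcript length 0.246.

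A hypothesis was that imprinted genes moved together, since Nap1l5 and Nnat are both imprinted; the list of 40 imprinted genes was written before this test. The 21 other tested members had a median log2 fold of 0.31 (SE 0.22), 7 were negative, and 0 were called by edgeR over all genes or adjusted over these 21 alone. Adjusted over all 23 tested members, Nap1l5, Nnat and Blcap passed (highest adjusted p 0.0465). The calls of Nap1l5 and Nnat prompted this test, so their passing here adds no evidence for the hypothesis. Blcap, named after its value was seen, had a log2 fold of -1.06. It passed only with Nap1l5 and Nnat in the adjustment, and not over the other 21 alone. The positive median of the 21 other members argues against a fall shared by the list as a whole, and limma's camera did not call the list either. The members were not divided by which parent's copy is expressed, so a fall confined to some imprinted genes was not tested.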
